A study of Mus musculus with 8 samples.

How the data were processed

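Gene expression was measured on Illumina mouse BeadChips, on which each probe is a 50-base sequence carried by beads and read as a fluorescence intensity. The tissue was the ventromedial hypothalamus, microdissected from female mice at postnatal day 10. There were 4 control samples, homozygous for a floxed Nkx2-1 allele, and 4 mutant samples of the same genotype that also carried Sf1Cre. Per the labels, total RNA was isolated with a column kit and amplified into biotin-labelled cRNA. The labels do not say whether a sample is 1 animal or a pool, so the p-values measure the spread between these samples.

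The deposited intensity values are average bead signals, per the file headers. The table's name calls them non-normalized, but the authors had subtracted background and scaled the arrays, as the values show: between 24.4% and 25.9% of probes per array were below 0 and the mean over all probes was 739.1 on every array. A detection p-value per probe and array was deposited beside each intensity, per the file headers. The authors also deposited quantile-normalized log2 values, in an annotated table and in the series' value table. Sorted within each genotype, the 2 tables held the same values for every probe. The annotated table gives the authors' log2 difference and unadjusted p-value per probe, and a score of 1, -1 or 0 for probes they called higher, lower or neither. The scanner software and the authors' normalization settings are not given in the sources used here. Another 4 per-sample columns of the annotated table were not used here.

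The intensity columns carry a genotype and a letter, and the labels carry replicate numbers, so letters were mapped to genotypes only. Background was corrected with the neqc method of limma 3.58.1 in R 4.3.3, which fits a normal and exponential mixture guided by the detection p-values, adds an offset of 16 and applies quantile normalization and log2. The offset compresses the fold changes of dim probes. Of 25697 probes, the 13288 with a detection p-value under 0.05 on at least 4 of the 8 arrays were tested, and they stood for 9916 genes. A linear model with empirical Bayes moderation compared mutant with control, two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A gene was counted by its tested probe with the highest mean. For single genes and list means, two-sided exact permutation tests used all 70 assignments of 4 arrays to the mutant group, whose smallest possible p is 0.0286. Symbols were updated through the Entrez identifier for 16938 probes and the RefSeq accession for 7420, using a gene table of assembly GRCm38.p6, and 1339 probes kept the array's symbol. That table served for names and gene order only, and the build of the files' probe coordinates is not given in the sources used here.

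Before the data were examined, 25 gene lists were fixed, and 23 had at least 3 tested members. They were tested with camera in limma, which asks whether a list moved relative to other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 23 lists. Camera with an estimated correlation, which also rests on fewer degrees of freedom, and fry were run beside it. Members were also adjusted over the list alone. Tac1 and Rprm were placed in the ventrolateral list from memory of published work on this mouse, so their result is not independent evidence.

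The rule for named genes was also fixed beforehand. It takes Nkx2-1, Nr5a1, Esr1, Pgr, Tac1, Rprm, Fezf1, Adcyap1, Bdnf and Sox14 wherever they were on the array, which Fezf1 and Sox14 were not under these symbols. It takes up to 12 genes per direction past the threshold with no overlap between genotypes. Where fewer than 5 pass, it takes the 5 genes with the smallest p in that direction, named as not past the threshold; these 5 were taken beyond any that passed. It then takes up to 4 members of each list with the smallest p, of which some are not reported here.

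The pipeline was tested on simulated arrays with the measured means and spreads, in which 200 of 13288 probes were changed in the mutant-control comparison. It recovered 65.7% of probes changed by 0.5 on the log2 scale, 82.1% of those changed by 1 and all 66 changed by 2, with 11 false calls among 176. These rates apply where many probes change, which loosens the adjusted threshold. With 1 probe called, a probe of median standard error passed only from a log2 difference of 0.968. A simulated shift of 0.3 in the microglia list was recovered and none of the other 22 lists was called, although simulated genes were independent of each other. The number of arrays limits the precision of every value.

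Alternatives covered the background correction, median scaling, the authors' processed values, the probe filter, the variance model, array weights, the replicate number as a block, the probe taken per gene, the list tests and leaving out each array in turn. Slide was not used as a block because no slide is given in the sources used here.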

Results

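Expression in the ventromedial hypothalamus, a nucleus that takes part in energy balance and female reproductive behaviour, was profiled at postnatal day 10 in female mice. The comparison asks what changes when the transcription factor gene Nkx2-1 is deleted by Sf1Cre, a recombinase driven from regulatory sequence of Nr5a1, which encodes steroidogenic factor 1 and marks cells of this nucleus. There were 4 control and 4 mutant arrays. Controls carried no Sf1Cre, so the design cannot tell an effect of the deletion from an effect of carrying the driver. Between 12952 and 13305 of 25697 probes were detected per array, and correlations between arrays over tested probes lay between 0.987 and 0.992. Levels below are log2 intensities after background correction and quantile normalization.

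Nkx2-1 itself was 5.23-fold lower in the mutant, with a mean level of 7.60 ± 0.46 (SD, n = 4) against 9.99 ± 0.62 (SD, n = 4) in controls. All 4 mutant values lay below all 4 control values, and the two-sided exact permutation p was 0.0286, the smallest this design allows. In limma the log2 difference was -2.39 (SE 0.32) with an adjusted p of 0.168, so the gene did not pass the threshold over all 13288 probes. With the authors' processed values the difference was -1.85 and the adjusted p 0.0180. The tested probe lies on chromosome 12 from 57633037 to 57633086 in the coordinates of the files, whose build is not given in the sources used here, and its position relative to the deleted part is not given either. A second Nkx2-1 probe was not above background on any of the 8 arrays.

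Nr6a1, which encodes the orphan nuclear receptor germ cell nuclear factor, rose 1.90-fold and was the 1 gene to pass the threshold. Its level was 7.38 ± 0.08 (SD, n = 4) in mutants and 6.45 ± 0.05 (SD, n = 4) in controls, a log2 difference of 0.92 (SE 0.07) with an adjusted p of 0.00263 in limma. Its probe lies on chromosome 2 from 38545461 to 38545510 in the files' coordinates. That probe was detected on all 8 arrays but was dim. Its deposited signals were 66.17 to 77.53 in controls and 144.6 to 165.3 in mutants, where the medians over all probes of an array were 40.34 to 44.29. With the authors' processed values the rise was 0.47 on the log2 scale, with an adjusted p of 0.0162. With the replicate number as a block on those values the call ended, at an adjusted p of 0.0673. No probe fell past the threshold. At an unadjusted limma p under 0.05 there were 454 higher and 413 lower probes, 867 in all, against 664.4 if p-values were uniform. The groups did not overlap for 3.43% of tested probes, where chance gives 2.86%.

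Besides Nkx2-1, the rule for named genes took 100 tested genes. Of these, 77 moved by over 1.5 times under some alternative, 63 of them by leaving out 1 array, so the sizes below are imprecise. The genes with the next smallest p-values did not pass the threshold. Among those with higher values in the mutant, Gal, which encodes the neuropeptide galanin, differed most in size: 11.54 ± 0.16 (SD, n = 4) in mutants and 10.30 ± 0.35 (SD, n = 4) in controls, or 2.35-fold, with a limma adjusted p of 0.168. Its adjusted p was 0.0399 without control array G, its highest control, and 0.0162 with the authors' processed values. It passed in no other fit: leaving out 1 array gave up to 0.811, and the other settings up to 0.352. The others were Usp14 (log2 0.38), Gpc6 (0.44), Efemp2 (0.67) and Vax2, with adjusted p-values between 0.611 and 0.627. Over the alternatives that kept all arrays, Gpc6 ranged from 0.18 to 0.56. Efemp2 had an adjusted p of 0.0399 without control array G and passed in no other fit, with up to 0.954 leaving out 1 array. Vax2 was not above background in any control array, so only a bound is given: at least 1.21-fold higher (log2 0.28), set by the dimmest detected probes. It holds for this processing only: under an alternative the fitted difference, taken against undetected controls, was smaller than this bound. Among genes with lower values, Tac1, the precursor gene of substance P, was at 12.66 ± 0.11 (SD, n = 4) in mutants against 13.14 ± 0.07 (SD, n = 4) in controls, 1.39-fold lower. Nmu, which encodes neuromedin U, was 1.91-fold lower. Both had a limma adjusted p of 0.391. Ldhd, detected in the controls but not above background in any mutant array, was at least 1.22-fold lower in this processing only. Under an alternative its fitted difference, taken against undetected mutants, was smaller than this bound. The 2 other Ldhd probes were not above background on any of the 8 arrays. A Prkaa2 probe differed by -0.35 and the second tested Prkaa2 probe by -0.0040 on the log2 scale. With a variance trend and robust estimation, Tac1, Nmu and Rprm had adjusted p-values of 0.00331, 0.0112 and 0.0294.

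**Figure D1:**
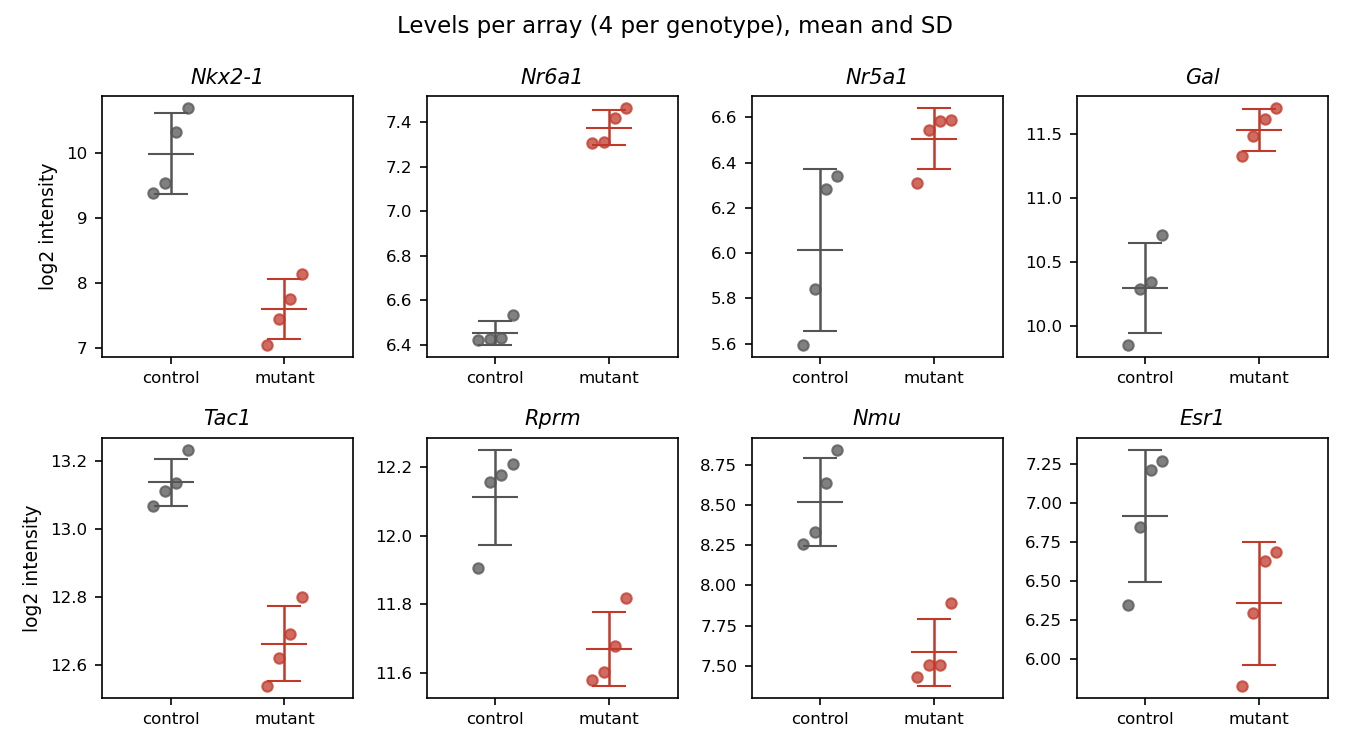
Log2 intensity on each array for 8 genes, with 4 control arrays in grey and 4 mutant arrays in red, and the mean and SD as bars. Values of Nkx2-1, Nr6a1, Gal, Tac1, Rprm and Nmu do not overlap between the genotypes, while those of Nr5a1 and Esr1 do, and Nr6a1 is the gene past the threshold.

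The ventrolateral and sex-steroid list, genes of the estrogen-responsive part of the nucleus, was lower in the mutant as a set, with a mean log2 difference of -0.19, a median of -0.21 and a camera adjusted p of 0.00218. With an estimated correlation the adjusted p was 0.209, so the call was not kept, and fry gave 0.0563 for a shift in 1 direction and 5.88e-05 for changes in either. Of its 10 tested members 7 were lower and 3 higher. No member passed over all probes, and Tac1 (-0.47) and Rprm (-0.44), a cell cycle arrest gene, passed adjusted over the list alone. Both were placed in the list from memory of published work on this mouse, so these list results are not independent evidence. Without them the camera p of the other 8 members was 0.0739, with a mean of -0.13, and fry was not run without them. Esr1, the estrogen receptor alpha gene, differed by -0.56 (SE 0.24) and was above background on 3 of 4 mutant arrays. Its two-sided exact permutation p was 0.114, and its difference ranged from -0.68 to -0.26 over the alternatives that kept all arrays. Nts, the neurotensin gene, differed by -0.31, and Pgr, the progesterone receptor gene, by -0.19.

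No shift of the general markers of the ventromedial nucleus was called. Of 16 tested members 12 were lower and 4 higher, the mean log2 difference was -0.01, the median -0.04 and the camera adjusted p 0.562 (0.721 with an estimated correlation). Nr5a1 differed by 0.49 (SE 0.16) at its brighter probe and by 0.31 at the other, both close to background, and neither passed. The brighter probe ranged from 0.19 to 0.66 over the alternatives that kept all arrays. Bdnf, a neurotrophin gene, differed by -0.15, Cckbr by -0.23, Crhr2 by 0.19 and Adcyap1, the PACAP precursor gene, by -0.06. Neuronal identity genes gave a mean of -0.02 over 8 members, with a camera adjusted p of 0.711, and Elavl4, Rbfox3, Tubb3 and Map2 lay between -0.20 and 0.17 at the probes used. A second Elavl4 probe of like brightness differed by -0.26 (unadjusted p 0.0346), against 0.17 at the probe used. Tested probes of 1 gene also disagreed in sign for Map2, Mbp, Nes, Birc5, Bbc3, Efna5 and Psmb7, named here or below.

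Genes of the arcuate nucleus, which lies beside the ventromedial nucleus, differed in both directions. The camera adjusted p for a shift was 0.323, with a mean of -0.01 and a median of 0.01, while fry for changes in either direction gave an adjusted p of 5.88e-05. Adjusted over the list alone, 3 of 12 members were higher, Gal (1.24), Sst (0.30) and Npy (0.36), and 1 was lower, the dopamine transporter gene Slc6a3 (-0.92). None of them passed over all probes.

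Peptide genes of other hypothalamic nuclei varied widely between arrays of 1 genotype. Avp, the vasopressin gene, was at 10.57 ± 2.55 (SD, n = 4) in mutants and 12.86 ± 0.82 (SD, n = 4) in controls, and Oxt, the oxytocin gene, at 10.10 ± 1.30 and 11.35 ± 0.35 (SD, n = 4 each). Their list of paraventricular, supraoptic and suprachiasmatic genes, which also held Lhx1 (0.47, detected on 1 of 4 control arrays) and Pou3f2 (-0.18), had a mean of -0.81 and a camera adjusted p of 0.292. Without mutant array H that p was 0.0437 at a mean of -1.18, and over probes detected on all 8 arrays 0.0164 at a mean of -1.24. The mean shrank to -0.40 without the filter on dim probes. Leaving out 1 array moved Avp between -3.36 and -1.44. The dorsomedial and lateral list had a mean of 0.31 and an adjusted p of 0.323, with Hcrt, the orexin gene, at 1.16 (SE 0.63), Grp at 0.46, Trh at 0.42 and Pmch at -0.32. Leaving out 1 array moved the mean between 0.09 and 0.50, Hcrt between 0.64 and 1.70, Trh between 0.16 and 0.83 and Pmch between -0.52 and -0.05. Thalamic and cortical genes had a mean of 0.08 (0.04 to 0.12 leaving out 1 array) and an adjusted p of 0.384, with Tcf7l2 at 0.40, Rora at 0.29, Satb1 at -0.16 and Ntng1 at 0.08.

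Lists of glial and vascular markers were higher in the mutant by camera with the preset correlation. With an estimated correlation none of these 5 lists passed: the adjusted p was 0.405 for astrocytes, mature oligodendrocytes, their precursors and microglia, and 0.518 for endothelium. No member passed over all probes or adjusted over the list alone. Astrocyte markers had a mean of 0.13 and an adjusted p of 0.00218 (0.05 and 0.0484 without mutant array H), with 9 of 10 higher, among them the glial transcription factor gene Sox9 (0.26), Aldoc (0.18), Fgfr3 (0.14) and Aqp4 (0.21). Mature oligodendrocyte markers had a mean of 0.29 and an adjusted p of 0.00218 (0.19 and 0.00608 without the filter on dim probes), with all 6 tested members higher, among them the myelin genes Mbp (0.47, and 0.43 and -0.06 at its other tested probes), Cnp (0.17) and Cldn11 (0.57). Oligodendrocyte precursor markers had a mean of 0.19 and an adjusted p of 0.00427, with all 6 higher, among them Olig1 at 0.20, Enpp6 at 0.40, Gpr17 at 0.20 and Pdgfra at 0.15. Microglial markers had a mean of 0.16, a median of 0.10 and an adjusted p of 0.0363, with 8 of 11 higher and 3 lower, and with Trem2 at 0.29, P2ry12 at 0.94 (SE 0.73) and Cx3cr1 at 0.11. Endothelial and pericyte markers had a mean of 0.16 and an adjusted p of 0.0167, with all 8 higher, among them Pdgfrb at 0.39, Rgs5 at 0.18, Ly6c1 at 0.12 and Tek at 0.15. The microglial call ended without control array C, D or F or mutant array B or H, with adjusted p-values of 0.0973, 0.125, 0.295, 0.167 and 0.216, and without the filter on dim probes, with 0.0928, and its mean was 0.11 without mutant array H. The endothelial call ended without control array F or mutant array B or H, with 0.126, 0.532 and 0.0568, and its mean ranged from 0.05 without mutant array B to 0.25 without mutant array E.

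Markers of other cells that a dissection can carry did not pass. Meningeal genes had a mean of 0.33 and a camera adjusted p of 0.323 (0.0435 without mutant array A and 0.0344 without mutant array E), with Ptgds at 0.90, Igf2 at 0.31, Dcn at 0.34 and Lum at 0.09. Leaving out 1 array moved the mean between 0.05 and 0.65, Ptgds between 0.30 and 1.55 and Igf2 between 0.0079 and 0.60. Choroid plexus genes had a mean of 0.35 and an adjusted p of 0.259 (0.0344 without mutant array E), with Clic6 at 0.37, Kl at 0.52 (detected on 2 of 4 control and 3 of 4 mutant arrays) and Ttr at 0.16. Their mean lay between 0.18 and 0.65 leaving out 1 array, and between 0.13 and 0.65 over the other alternatives. Tanycyte and ependymal genes had a mean of 0.01, a median of -0.02, a camera direction of lower and an adjusted p of 0.976, with Col23a1 at -0.17, Nes at 0.20, Rarres2 at 0.15 and Foxj1 at -0.03. Haemoglobin genes and Alas2 had a mean of 0.05 and an adjusted p of 0.876, with Alas2 at 0.10, Hbb-b2 at 0.20, Hbb-b1 at -0.14 and Hba-a1 at 0.04. None of the 8 anterior pituitary genes was tested, since their probes did not reach the detection minimum.

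**Figure D2:**
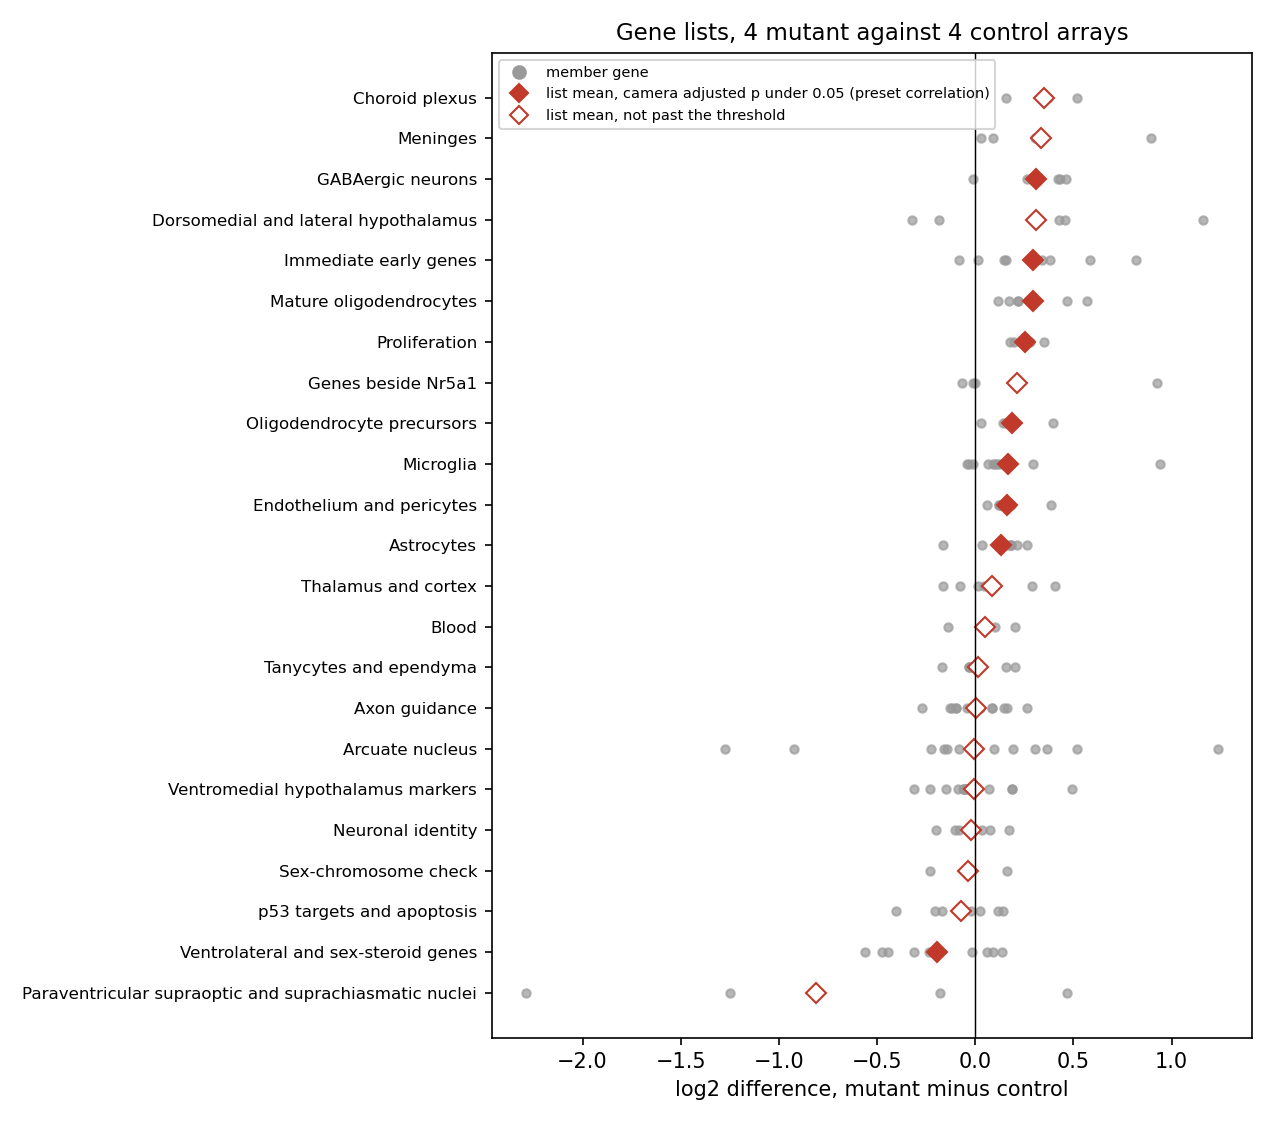
Log2 difference, mutant minus control, for 23 gene lists, with member genes as grey points and list means as diamonds, filled where the camera adjusted p with the preset correlation was under 0.05. Of the 9 filled diamonds 8 lie above 0 and the ventrolateral list lies below, and none of the 9 lists passed with an estimated correlation.

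GABAergic neuron markers were also higher by camera, with a mean of 0.31, 5 of 6 higher and an adjusted p of 0.0167 (0.430 with an estimated correlation). The GABA-synthesising enzyme gene Gad1 differed by 0.43, Dlx1 by 0.46, Slc32a1 by 0.26 and Meis2 by 0.42. The call ended without control array F or mutant array B or E, with adjusted p-values of 0.211, 0.0581 and 0.0808, and without the filter on dim probes, with 0.403. Its mean was 0.15 without control array F and 0.13 without the filter. Immediate early genes, transcribed within minutes of stimulation, had a mean of 0.29, 7 of 8 higher and an adjusted p of 0.0167 (0.405 with an estimated correlation), with Egr2 at 0.82 (detected on 2 of 4 control and 3 of 4 mutant arrays), Fos at 0.58, Egr4 at 0.38 and Dusp1 at 0.16. That call ended without control array F (0.126) or mutant array E (0.373), and over probes detected on all 8 arrays (0.0601). Its mean was 0.19 with the authors' processed values or without control array F, and 0.17 without mutant array E. Proliferation genes had a mean of 0.25, all 4 higher and an adjusted p of 0.00436 (0.405 with an estimated correlation), with Ccnb1 at 0.28, Cdk1 at 0.35, Birc5 at 0.18 and Top2a at 0.20, and the adjusted p was 0.0581 without mutant array B. Their mean was 0.15 without mutant array B or without the filter, and 0.13 with the authors' processed values. Genes of p53 and apoptosis had a mean of -0.07 and an adjusted p of 0.293, with Bax at -0.17, Bbc3 at -0.21 and Ccng1 at 0.11. Axon guidance genes had a mean of 0.0021 and an adjusted p of 0.961, with Epha5 at 0.26, Sema3a at -0.27, Robo1 at 0.16 and Efna5 at -0.10. Of the Nkx2-1 target genes of lung and thyroid, fewer than 3 reached the detection minimum, so that list was not tested.

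Genes beside Nr5a1 on chromosome 2 were listed because the Cre driver carries regulatory sequence from there. Camera gave an adjusted p of 0.173 for 4 tested members, with a mean of 0.21 and a median of -0.01, and 0.0403 without mutant array A. Fry gave 0.0247 for a shift in 1 direction. Nr6a1 passed over all probes, while Rpl35 (-0.07), Psmb7 (-0.01) and Wdr38 (-0.0013) did not. No tested gene lies between Nr5a1 and Nr6a1 in the reference order. The 15 tested probes of the 6 nearest tested genes on each side lay between -0.19 and 0.10, and none had an unadjusted limma p under 0.05. By the same measure the brighter Nr5a1 probe had 0.015 and the other 0.0507.

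**Figure D3:**
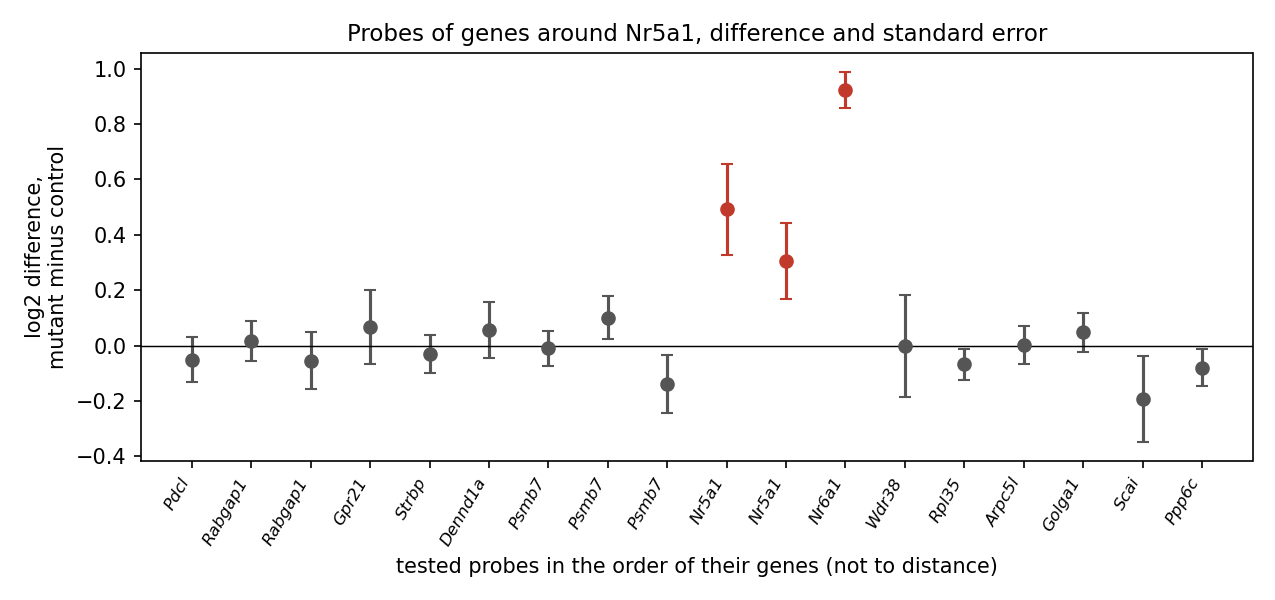
Log2 difference, mutant minus control, with its standard error for each tested probe of Nr5a1, Nr6a1 and the 6 nearest tested genes on each side, in gene order and not to distance. The Nr6a1 probe (0.92) and both Nr5a1 probes (0.49 and 0.31), in red, lie above the other 15 probes, which range from -0.19 to 0.10.

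Sex-linked genes were a check of the labels, which give all mice as female. Xist, expressed from the inactive X chromosome, was detected on all 8 arrays at both probes and differed by 0.16. Of the Y-linked genes, the probes of Kdm5d and Eif2s3y and 2 of 3 Ddx3y probes were not detected on any array. The remaining Ddx3y probe (-0.23) and a Uty probe (-0.05) were detected on all 8 arrays, and why was not tested. The list's camera adjusted p was 0.732. It compares genotypes over a list that mixes Xist with Y-linked genes, so it cannot check the sex of the samples.

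In the authors' deposited table, 88 probes were called higher and 69 lower in the mutant. In the authors' deposited table every called probe had an unadjusted p of at most 0.00487, and a limma fit of the deposited values gave a smallest p of 0.005003 among uncalled probes. A threshold of 0.005 therefore separates the calls, and 128.5 of 25697 probes would lie under it if p-values were uniform. After Benjamini-Hochberg adjustment of that fit over all probes, 4 of the 157 calls had an adjusted p under 0.05: Nr6a1 and Gal higher, Nkx2-1 and Tac1 lower.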

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

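The tests of Nr6a1, of the glial and vascular lists and of the ventrolateral list were chosen after the results were seen, while the counts over other splits of the arrays were planned before they were computed. A value far from the 3 others of its genotype was found in 14 of 250 groups of 4, where chance alone gives about 1 in 20, or 12.5. The number given for each is the gap to the nearest other array divided by the range of the group.

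In controls, array C stood apart for Hcrt (0.943; 9.90 against 7.66 to 7.79), Rprm (0.830; 11.91 against 12.16 to 12.21), the dorsomedial and lateral list mean (0.934) and the ventrolateral list mean (0.877). Array D stood apart for Rarres2 (0.944; 7.93 against 9.03 to 9.09) and the tanycyte list mean (0.865). Array F stood apart for Fgfr3 (0.923) and Tcf7l2 (0.834), and array G for Nr6a1 (0.948; 6.53 against 6.42 to 6.43). In mutants, array A stood apart for Egr2 (0.951; 5.70 against 6.90 to 6.97), array B for Ddx3y (0.837) and Nr5a1 (0.844), and array H for Nmu (0.831) and Uty (0.912).

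The background correction and normalization tried do not account for the rise of Nr6a1: over no background correction, median scaling and the authors' processed values the highest adjusted p was 0.0162. With the replicate number as a block on the authors' values it was 0.0673, although no label says that those numbers pair the samples. Extra copies of the Nr5a1 region carried with the Cre driver remain a hypothesis. Nr5a1 itself, close to background, was 0.49 higher (0.19 to 0.66 over the alternatives that kept all arrays). Its adjusted p was 0.737 and its unadjusted limma p 0.015, with 0.0507 at its second probe. None of the 15 probes of the nearest other genes had an unadjusted limma p under 0.05. These values do not decide it. Regulation of Nr6a1 by loss of Nkx2-1 stays open too and was not tested, since every mutant carries both the deletion and the driver.

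For the higher glial and vascular lists, correlation between the genes of a list may account for the calls, but the test cannot decide it. With it estimated, the lowest camera adjusted p of the 5 lists was 0.405, and their estimated correlations lay between 0.127 and 0.721. That test also rests on fewer degrees of freedom. The ventrolateral list lost its call too, at 0.209, though its estimated correlation was -0.02. A lower share of neurons in the mutant dissections cannot be told apart from a change in glia. Oligodendrocyte and tanycyte list means moved apart by 0.28 with a two-sided exact permutation p of 0.257, and the neuronal list mean differed by -0.02 (exact p 0.429). These values do not decide it, and the GABAergic neuron list, at 0.31, was higher as well. An effect of the genotype on glia was not tested apart from it.

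For the lower ventrolateral list, loss of ventromedial cells as a whole is not excluded. The ventrolateral list fell below the ventromedial list by -0.19 on the log2 scale, and by -0.15 with Nr5a1 left out of the latter, each with a two-sided exact permutation p of 0.0286, the smallest possible. Tac1 and Rprm, however, were placed in the list from memory of published work on this mouse. Without them the difference was -0.12 (exact p 0.0857), and -0.09 (exact p 0.143) with Nr5a1 left out as well. Tac1 and Rprm may carry much of the shift: without them the camera p of the other 8 members was 0.0739, with a mean of -0.13. A change in the ventrolateral part in the mutant remains a hypothesis, and a difference in how much of that part was dissected was not tested.

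Other splits of the 8 arrays into 4 and 4 do not exclude chance for the counts. The real split called 1 probe and 1 gene, and 8 of 35 splits called at least as many of each, with up to 9 probes and 7 genes. It gave 9 gene lists, and 2 of 35 splits gave at least as many, with up to 11. At the threshold that separates the authors' calls the real split gave 157 probes, and 5 of 35 splits gave at least as many, with up to 315. Why the split with 9 probes called several times the real count was not tested.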

How the results depend on the processing

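The replicate block and the exact tests of list means were chosen after the data were seen. The count of 1 changed probe, and of 1 changed gene, was also 1 with no background correction, median scaling, no filter on dim probes, detection on all 8 arrays and array weights. It was 3 with the authors' processed values and 4 with a variance trend and robust estimation, and leaving out 1 array gave 1 to 4, with 4 without control array G. The cause was not tested. The probe with the smallest p per gene also gave 1. Nr6a1 was among the calls in each of these fits, with log2 differences from 0.47 to 1.06.

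No label says that replicate numbers pair the samples, and the values gave little sign of it. Deviations of same-numbered samples correlated at -0.07, -0.02, -0.13 and 0.16, and only control 4 correlated best with the mutant of its own number. With so few arrays a weak pairing is not excluded. A replicate block could be run on the authors' processed values, which carry the numbers; it called 0 probes and 0 genes by limma, with 937 probes at an unadjusted p under 0.05 and adjusted p-values of 0.0528 for Nkx2-1 and 0.0673 for Nr6a1. It changed no list count, which stayed at 9.

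Nkx2-1 was lower in every fit. It passed with the authors' processed values (-1.85, adjusted p 0.0180); its adjusted p over the other settings, leaving out arrays aside, reached 0.518, and leaving out 1 array gave -2.58 to -2.15 on the log2 scale.

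Of 23 lists, 9 passed with camera at the preset correlation. The count was 0 with an estimated correlation, 1 with fry in 1 direction and 3 with fry in either direction. Fry in 1 direction called the genes beside Nr5a1, which are not among the 9. In either direction it called these, the arcuate list and the ventrolateral list, of which only the last is among the 9. Exact permutation of array means called 0 lists, with an unadjusted p under 0.05 for the genes beside Nr5a1 alone. That test could hardly call any list, since its smallest p, 0.0286, is adjusted over 23 lists. These tests ask other questions or allow for correlation by construction. Leaving out 1 array gave 5 to 11, with 5 without control array F or mutant array B.

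Signs changed only for values that were not past the threshold. With array weights Alas2 was -0.0059, Hba-a1 -0.022 and Psmb7 0.0017, and the blood and axon guidance list means -0.019 and -0.0075. Wdr38 was 0.0084 with median scaling and 0.0064 with the authors' processed values, with or without the replicate block. The axon guidance list was -0.0088 with no filter. For the tanycyte list camera's direction turned while the mean kept its sign, at 0.023 with median scaling and 0.039 with array weights. The cause was not tested. Leaving out 1 array gave ranges across 0 for Alas2 (-0.15 to 0.27), Dcn (-0.027 to 0.68), Foxj1 (-0.14 to 0.076), Hba-a1 (-0.10 to 0.17), Hbb-b1 (-0.40 to 0.33), Hbb-b2 (-0.36 to 0.71), Lum (-0.010 to 0.22), Map2 (-0.0027 to 0.11), Psmb7 (-0.027 to 0.013), Rarres2 (-0.13 to 0.34), Ttr (-0.24 to 0.60), Uty (-0.092 to 0.039) and Wdr38 (-0.13 to 0.18). The same held for the arcuate (-0.19 to 0.10), tanycyte (-0.14 to 0.14), blood (-0.11 to 0.21), axon guidance (-0.029 to 0.034), ventromedial (-0.038 to 0.022) and sex-chromosome (-0.078 to 0.0097) list means. Over the other settings means crossed 0 for the arcuate (-0.21 to 0.13), ventromedial (-0.050 to 0.0076) and tanycyte (-0.0078 to 0.039) lists.

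The authors' annotated table was not run apart, as its values equal the series' value table, and slide was not run. Dim probes limit the values of Nr5a1, Esr1, Pgr, Vax2, Ldhd, Egr2, Kl, Lhx1, Hbb-b2, Lum and Wdr38, which were not above background on every array. Over the other settings Kl ranged from 0.22 to 1.43, Egr2 from 0.34 to 1.07 and Lhx1 from 0.18 to 0.87. Nr6a1 was above background on every array but was dim too, and ranged from 0.47 to 1.06.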

Other observations

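A Cfl1 probe, outside the rule for named genes and chosen after its values were seen, was at 4.77 to 4.95 on control arrays C, D and F and at 8.89 on control array G, while the 4 mutant arrays lay between 8.54 and 8.91. The probe was detected on 5 of the 8 arrays. Without control array G it had the lowest adjusted p of any call, 3.36e-06, and with all arrays 0.737. Array G was the 1 control at the mutant level, so leaving it out removes the overlap and that p is not evidence of a difference. Avp spanned 59.6-fold and Oxt 8.70-fold between the lowest and highest of the 8 arrays; on mutant array H their deposited signals were 13930 and 3717, where the controls had 3947 to 15760 and 1941 to 3469.

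Biological process terms in the annotated table gave no call. Of 184 terms with 10 to 300 tested genes, chosen for testing after the data were seen, none passed with camera, the lowest adjusted p was 0.499, and 13 had an unadjusted p under 0.05 where 9.2 would if p-values were uniform.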
